A study of Mus musculus with 9 samples.

How the data were processed

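RNA from Reissner's membrane of adult mice was measured on 9 Affymetrix expression arrays, 3 each for fresh tissue, tissue incubated for 24 h and tissue incubated for 24 h with dexamethasone, per the labels. Membranes were dissected free-hand, pooled and kept as explants where incubated, and 3 chips were used per biological sample, per the labels' design text. RNA was purified with an RNeasy Micro kit and amplified with a small-sample protocol of 2 rounds of in vitro transcription, per the labels' protocols. The deposited values were linear intensity signals, 1 per probe set, which the authors scaled on each array over all probe sets to a target signal of 500 with a normalization factor of 1, per the labels' description. Among the deposited signals the mean over all probe sets, trimmed by 2% at each end, was 500 on every array. The name and version of the software that summarised probes into signals are not given in the sources used here, and the analysis plan treated the values as MAS5-type signals. No detection calls were used, so a signal of 200 served as the working floor.

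Of 45101 probe sets, 64 were control probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none in the annotation used, and the 1-symbol probe sets covered 18193 genes. For 204 probe sets the gene ID was not in the list of genes used, and their symbols were taken as given. The fixed gene lists held 641 entries, of which 580 matched the array, 6 of them through an older or newer symbol.

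Tested probe sets reached a signal of 200 on at least 3 of the 9 arrays, with control probe sets excluded, which left 18913. Genes above 200 in 1 group alone were tested through that group, so they could hardly be called lower in it. Signals were analysed as the log2 of signal plus 32. A linear model with 1 mean per group was fitted to all 9 arrays in limma 3.58.1 (R 4.3.3), with eBayes and an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method over the probe sets of each comparison. A probe set was called at an adjusted p under 0.05, and 2-fold counts also needed an absolute log2 change of at least 1. The main comparisons were incubated against fresh and dexamethasone against incubated, and dexamethasone against fresh was secondary. Each gene was represented by the tested probe set with the highest mean log2 signal. Gene lists with at least 3 measured members were tested with camera (preset correlation of 0.01, and again with an estimated correlation) and with fry, and adjusted over the 32 lists. List members were also adjusted over their list alone. Tables were handled with data.table (1.17.8), Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures were drawn with matplotlib 3.10.9.

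The groups, comparisons, tests, gene lists, alternative settings and the rule for named genes were fixed before the data were examined. The rule named, in each main comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap. It also named up to 4 members of each list with the smallest adjusted p, more where a list was described in full, and 13 sodium transport, receptor and receptor target genes in every case, 1 of which is not reported here. Members with both group means under 200 were passed over, since no fold is given for them. Vcam1 on incubation, and Ccl2, Cxcl1 and Serping1 with dexamethasone, fell outside the rule and were chosen after their values were seen. Where the 3 arrays of one group all lay under 200 and the other group's mean lay above it, the change was given as at least that mean over 200. Probe sets whose names end in _s_at or _x_at, which may hybridize to several transcripts, stood for Angptl4, Asns, C1qb, C1s1, Ccn1, Cnp, Cxcl1, Dbp, Dmp1, Fdft1, Gja1, Gsn, Gstm1, H2-D1, H2-K1, Hspe1, Ifi202b, Lrp2, Mcm3, Mcm5, Mcm7, Mt1, Ndrg1, S100a8, Slc4a1, Srf, Srxn1, Stk39 and Tpi1.

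The fit was tested on simulated data with known changes, whose means and spreads were taken from the fit to the arrays. Noise was drawn from a normal distribution, as the model assumes, so departures from it were not tested. At log2 changes of 0.25, 0.5 and 1 it recovered 16.4%, 74.6% and 98.5% of changed probe sets for incubated against fresh, with 5 false calls. The shares were 14.9%, 71.6% and 100% (6 false calls) for dexamethasone against incubated and 16.4%, 65.7% and 97.0% (6 false calls) for dexamethasone against fresh. The median SD of log2 signals over tested probe sets was 0.0874 in fresh, 0.0916 in incubated and 0.0909 in dexamethasone arrays. For the 9 hybridization controls it was 0.0452, 0.0577 and 0.0707, against 0.0655, 0.0790 and 0.0760 for probe sets of like signal. These spreads are between chips, so the precision across animals is not known from them.

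Alternative settings chosen beforehand were quantile normalization, median centring, pseudocounts of 1 and 100, no filter or floors of 100 and 400, eBayes without the trend, the 2 compared groups alone, 1 probe set per gene, the array letter as a block, and leaving out each array in turn. Scaling to the bioB, bioC, bioD and cre hybridization controls was added after those controls had been seen, and dividing the incubated arrays between the comparisons was added after the results had been. Sets of further neutrophil, erythroid, leukocyte-wide, interferon-induced, neuronal and glial genes, none of them in the fixed lists, were used in the closing section.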

Results

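Gene expression was measured in Reissner's membrane, the thin avascular sheet that separates the scala media from the scala vestibuli of the cochlea. An epithelial layer faces the endolymph and a mesothelial layer faces the perilymph. The tissue came from adult mice and was dissected by hand. Membranes were either extracted at once (fresh) or kept as explants for 24 h without (incubated) or with (dexamethasone) the synthetic glucocorticoid dexamethasone at 100 nM. Each of the 3 groups had 3 oligonucleotide arrays, lettered A to C, for 9 arrays in all. The dose on the labels of dexamethasone arrays B and C is typed in mM, while the label of array A and the design text give 100 nM. Membranes were pooled and 3 chips were hybridized per biological sample, per the design text, so p-values here measure only the spread between arrays, which may be technical. The number of arrays limits the precision of every value.

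Array signals were on a linear scale with a trimmed mean of 500 on every array. A signal of 200 or more was reached by 39.4 ± 0.012% of probe sets in fresh arrays, 36.2 ± 0.18% in incubated arrays and 37.6 ± 0.18% in dexamethasone arrays (SD, n = 3). Between arrays of one group, Pearson's r of log2 signals across probe sets was 0.992 to 0.993. It was 0.837 to 0.838 between incubated and fresh arrays, 0.956 to 0.959 between dexamethasone and incubated arrays and 0.814 to 0.818 between dexamethasone and fresh arrays. No pair of arrays held identical values. Changes below are log2 differences of group means ± SE from a single limma fit over 18913 probe sets, with n = 3 per group. They covered 10242 genes, and 1849 of them had no gene symbol and 492 had several. Where all 3 arrays of one group lay under 200, the change is a lower bound against that level instead. Gene lists were tested against all other genes with camera over 32 lists.

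The first comparison set 24 h in culture against fresh tissue. Fosl1, a subunit of the AP-1 transcription factor, had one of the largest rises: Fosl1 rose at least 8.59-fold (adjusted p = 1.08e-13). Annexin A3 and galectin-3 transcripts reached the highest signals among the 8 largest rises, with 12147 ± 492 for Anxa3 and 13169.6 ± 388 for Lgals3 in incubated arrays (SD, n = 3). Anxa3 rose by 5.05 ± 0.071 (adjusted p = 3.52e-14) and Lgals3 rose by 4.85 ± 0.062 (adjusted p = 1.89e-14). The chemokine gene Ccl2 rose at least 11.4-fold (adjusted p = 4.15e-12), and Igfbp3 rose by 4.88 ± 0.090 (adjusted p = 3.54e-13), which encodes a binding protein of insulin-like growth factors. The remaining largest rises were Dusp5 (at least 11.3-fold higher), an ERK phosphatase, Sprr1a (at least 9.72-fold higher), a cornified envelope precursor, and Ifi202b (at least 17.3-fold higher), an interferon-inducible gene whose probe set may also hybridize to related transcripts (adjusted p at most 1.62e-11).

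The 8 largest falls included transcripts of cochlear fibrocytes, neurons and calcium-binding proteins, with fresh signals of 3318 to 15914 (Nefh and Coch). Coch, which encodes the extracellular matrix protein cochlin, went from 15914 ± 353 to 152 ± 7.58, and Coch fell at least 79.6-fold (adjusted p = 1.25e-15). Otos fell at least 66.2-fold (adjusted p = 1.91e-15), the gene of otospiralin, a protein of inner ear fibrocytes. The synaptic gene Snap25 fell at least 23.2-fold (adjusted p = 5.91e-12), and the neurofilament genes Nefl fell at least 32.4-fold (adjusted p = 5.11e-12) and Nefh fell at least 16.6-fold (adjusted p = 4.04e-12). Calb2 fell at least 34.6-fold (adjusted p = 3.96e-12), the calretinin gene, and S100b fell by 5.91 ± 0.17 (adjusted p = 9.75e-12), another calcium-binding protein. Dnase1 fell at least 50.0-fold (adjusted p = 9.39e-13), which encodes a secreted deoxyribonuclease.

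The 3 subunits of the epithelial sodium channel, which carries sodium from endolymph into the epithelium, were all lower after 24 h in culture. Scnn1a fell by 1.08 ± 0.063 (adjusted p = 7.24e-09) from a fresh signal of 1982 ± 136 to 918 ± 36.3, Scnn1b fell by 1.20 ± 0.066 (adjusted p = 3.91e-09) and Scnn1g fell by 0.78 ± 0.065 (adjusted p = 2.26e-07). Of 21 genes measured in the fixed list of sodium transport and its corticosteroid control, 2 rose, 17 fell and 2 did not pass the test. The counts adjusted over the list alone were the same, and the list was lower than other genes (camera adjusted p = 0.00182, adjusted p = 0.0382 with an estimated correlation). The falls included Atp1b2 (-3.04 ± 0.068), Fxyd6 (-3.17 ± 0.10) and Atp1b1 (-0.39 ± 0.045), subunits or modulators of the sodium pump, the kinase gene Wnk4 (-2.89 ± 0.10) and the ubiquitin protease gene Usp2 (-1.27 ± 0.060) (adjusted p at most 4.73e-06). Atp1b2 was also listed as a marker of strial marginal cells, and markers of these and other adjoining cells fell too, as given below. Of the corticosteroid receptors, Nr3c1 (glucocorticoid) and Nr3c2 (mineralocorticoid), Nr3c1 fell by 0.77 ± 0.072 (adjusted p = 6.15e-07) and Nr3c2 fell by 0.30 ± 0.062 (adjusted p = 7.44e-04). Scaling the arrays to their hybridization controls, instead of to the whole array, turned the Nr3c2 change positive and ended the call of Atp1b1, and 6 genes of the list rose and 12 fell. Hsd11b1 fell at least 1.92-fold (adjusted p = 8.30e-06), which encodes an enzyme that regenerates active glucocorticoid. The kinase gene Sgk1 (-0.054 ± 0.052, adjusted p = 0.362), a mediator of corticosteroid action on the channel, did not pass the test, with a fresh signal of 8352 ± 483, although it passed as a fall with quantile normalization (-0.18). Nedd4l rose by 0.96 ± 0.047 (adjusted p = 1.56e-09), which encodes the ubiquitin ligase that removes the channel from the membrane, while 2 of its 3 other probe sets went the other way past the test.

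Potassium, chloride and calcium handling genes were also lower. Of 12 potassium and chloride channels and transporters, 11 fell and none rose (12 fell when adjusted over the list alone; camera adjusted p = 1.11e-04, adjusted p = 0.0382 with an estimated correlation). They included Slc26a4 (-2.87 ± 0.066), the pendrin anion exchanger, Slc12a2 (-1.75 ± 0.047), a sodium, potassium and chloride cotransporter, and the potassium channels Kcnj16 (at least 8.06-fold lower) and Kcnk2 (-2.49 ± 0.093) (adjusted p at most 1.12e-10). Of 12 calcium transport and binding genes, 1 rose and 8 fell, among them the pump Atp2b2 (-1.66 ± 0.066), Calb1 (at least 2.84-fold lower) and Trpm4 (-1.09 ± 0.059) (camera adjusted p = 0.0197, adjusted p = 0.0804 with an estimated correlation). Of 7 purinergic and other receptor genes, 6 rose and none fell, including P2rx2 (1.92 ± 0.050), an ATP-gated channel, P2rx4 (0.49 ± 0.063), Entpd2 (0.80 ± 0.086) and Panx1 (at least 1.69-fold higher) (camera adjusted p = 0.0132, adjusted p = 0.0770 with an estimated correlation). Among 8 water channel and gap junction genes, 5 fell and 2 rose, and the list did not pass its test (camera adjusted p = 0.129). The connexins Gjb6 (at least 32.2-fold lower), Gjb2 (-3.44 ± 0.056) and Gja1 (at least 4.58-fold lower) fell, and the water channel gene Aqp5 (2.01 ± 0.11) rose. Adjusted over the list alone, the calcium, purinergic and water channel counts were unchanged. The fixed lists also held Slc12a2 as a strial marginal marker, Gjb6 as a supporting cell marker and Aqp1 as a fibrocyte marker. The lists of these cells had medians of -1.75, -3.08 and -4.26. With changes against a group under 200 held to that level, the medians were -1.33, -1.31 and -4.08. The falls were therefore not set apart from those of adjoining cells.

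Epithelial cell markers were higher in culture, while markers of adjoining cells were mostly lower, as given below. A change in the shares of cells was not set apart from a change within epithelial cells. Of 11 epithelial cell markers, 10 rose and none fell (camera adjusted p = 4.86e-04, adjusted p = 0.0483 with an estimated correlation). Krt8 went from 4026 ± 178 to 18103 ± 687, and the keratins Krt8 (2.16 ± 0.053), Krt18 (1.72 ± 0.054) and Krt19 (1.26 ± 0.051) rose. Of 20 epithelial junction genes, 14 rose and 4 fell (camera adjusted p = 0.00546, adjusted p = 0.0804 with an estimated correlation). The tight junction genes Cldn6 (4.25 ± 0.054), Cldn4 (3.17 ± 0.046) and Cldn7 (1.39 ± 0.052) rose while Cldn8 (-1.69 ± 0.068) fell. Mesothelial and fibroblast markers moved both ways, 4 higher and 7 lower of 12 (camera adjusted p = 0.327): the mesothelial surface gene Msln rose at least 6.01-fold (adjusted p = 3.32e-12), whereas Thy1 fell at least 5.09-fold (adjusted p = 1.97e-10). Among 23 collagen and matrix genes, 8 rose and 12 fell (camera adjusted p = 0.331), with a list median of -0.15 that turned positive with hybridization-control scaling, with 12 rises and 10 falls. Col4a1 (1.65 ± 0.056), a basement membrane collagen, rose, and the small proteoglycans Lum (at least 9.17-fold lower) and Dcn (-1.45 ± 0.058) and the fibrillar collagen Col11a1 (at least 3.55-fold lower) fell. Of 17 matrix protease and wound response genes, 9 rose and 7 fell (camera adjusted p = 0.140). The rises included the growth factor Hbegf (2.80 ± 0.063), the metalloproteinase inhibitor Timp1 (at least 15.7-fold higher), the urokinase receptor Plaur (at least 5.05-fold higher) and the matricellular gene Ccn1 (3.56 ± 0.11). For every gene in this paragraph the adjusted p was at most 3.19e-10, and no list count changed when adjusted over the list alone.

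Inflammatory genes were higher after 24 h, and so were 7 of 10 macrophage markers, as given below. Of 17 cytokine, chemokine and enzyme genes, 14 rose and 3 fell, the same as adjusted over the list alone (camera adjusted p = 2.55e-05, adjusted p = 0.0361 with an estimated correlation). Csf1 (2.93 ± 0.066), a macrophage growth factor, Ccl5 (at least 4.85-fold higher), a chemokine, and Relb (at least 5.94-fold higher), an NF-kB subunit, rose with Ccl2, and the adhesion molecule gene Vcam1 (-0.35 ± 0.075) fell, a change that hybridization-control scaling removed. Of 19 complement, MHC and interferon genes, 14 rose and 1 fell (camera adjusted p = 6.62e-04, adjusted p = 0.0382 with an estimated correlation), again as when adjusted over the list alone. The antiviral genes Ifit1 (2.71 ± 0.066) and Ifit3 (2.42 ± 0.080) and the class I genes H2-K1 (1.22 ± 0.053) and H2-D1 (1.08 ± 0.049) rose. Immediate early genes were higher too, with 18 of 21 past the test upward and 2 downward (camera adjusted p = 2.46e-05, adjusted p = 0.0361 with an estimated correlation), the same adjusted over the list alone. Besides Fosl1 they included Ier3 (2.60 ± 0.052), Myc (at least 3.93-fold higher) and Jun (2.23 ± 0.060). The largest adjusted p among the genes given here was 9.92e-04.

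Cholesterol synthesis and energy metabolism genes were mostly higher. 12 of 16 cholesterol synthesis genes rose and 1 fell (camera adjusted p = 9.56e-04, adjusted p = 0.0382 with an estimated correlation), among them the sterol enzymes Msmo1 (1.81 ± 0.053), Sc5d (1.98 ± 0.087), Idi1 (1.45 ± 0.065) and Cyp51 (1.86 ± 0.085). Of 18 glycolysis and hypoxia genes, 12 rose and 5 fell (camera adjusted p = 0.0307, adjusted p = 0.0888 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.106). Ldha (1.16 ± 0.048), Hk2 (1.93 ± 0.10), Tpi1 (0.82 ± 0.046) and the glucose transporter Slc2a1 (0.74 ± 0.047) rose. Of 25 oxidative phosphorylation genes, 18 rose and 3 fell (camera adjusted p = 0.00393, adjusted p = 0.206 with an estimated correlation), with the respiratory chain gene Ndufa4 (0.90 ± 0.051) and the electron carrier gene Cycs (0.71 ± 0.040) among the rises. Of 18 heat shock genes, 12 rose and 3 fell (camera adjusted p = 0.0184, adjusted p = 0.0870 with an estimated correlation), including Hspb8 (1.57 ± 0.052), Hspe1 (1.02 ± 0.073) and Hspa1a (0.86 ± 0.062). Oxidative stress genes gave 10 rises and 5 falls of 18 (camera adjusted p = 0.0620), led by the thioredoxin system genes Txnrd1 (1.59 ± 0.061), Txn1 (1.01 ± 0.043) and Srxn1 (1.75 ± 0.083), and the list passed the test without fresh array B (adjusted p = 0.0421). Unfolded protein and amino acid stress genes rose in 14 cases and fell in 11 of 25 (camera adjusted p = 0.192): the folate enzyme Mthfd2 (3.10 ± 0.058) and asparagine synthetase Asns (2.08 ± 0.062) rose, and Herpud1 (-1.26 ± 0.051) fell. Cell cycle genes moved both ways, 10 up and 5 down of 15 (camera adjusted p = 0.154): the replication genes Mcm3 (1.51 ± 0.072) and Pcna (1.02 ± 0.056) rose while the proliferation marker Mki67 (at least 7.16-fold lower) fell. With hybridization-control scaling the rises and falls were 24 and 1 for oxidative phosphorylation, 14 and 1 for glycolysis, 14 and 3 for oxidative stress and 15 and 6 for unfolded protein genes. For these genes the adjusted p was at most 5.47e-08, and all list counts were the same adjusted over the list alone.

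Clock output genes and transcripts of the glucocorticoid receptor's targets were examined as further lists. Of 15 circadian clock genes, 11 fell and 4 rose (camera adjusted p = 0.0429, adjusted p = 0.0921 with an estimated correlation), and leaving out incubated array C (adjusted p = 0.0544) or quantile normalization (adjusted p = 0.0522) ended the call. The clock output factors Dbp (-1.96 ± 0.064) and Tef (-1.32 ± 0.058) and the period genes Per1 (-2.13 ± 0.10) and Per3 (-1.38 ± 0.060) fell (adjusted p at most 6.53e-10). Of 27 receptor targets, 13 fell, 8 rose and 6 did not pass the test (camera adjusted p = 0.310). The list's median of -0.085 turned positive with hybridization-control scaling, with 14 rises and 12 falls. Sult1a1 (at least 8.95-fold lower), Klf15 (-2.76 ± 0.070), Zbtb16 (-2.32 ± 0.073), Tsc22d3 (at least 4.97-fold lower) and Fkbp5 (-1.45 ± 0.10) fell, and the metallothionein gene Mt1 (2.30 ± 0.053) rose (adjusted p at most 4.25e-08). Adjusted over the list alone, both lists gave the same counts.

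Markers of cell types next to the membrane were mostly lower after culture. All 8 markers of spiral ligament and limbus fibrocytes fell (camera adjusted p = 2.55e-05, adjusted p = 0.0382 with an estimated correlation), with Car3 (-4.60 ± 0.081) and the borate transporter family gene Slc4a11 (-3.93 ± 0.075) beside Coch and Otos. 9 of 10 neuron markers fell and none rose (camera adjusted p = 4.51e-04, adjusted p = 0.0382 with an estimated correlation), including Nefm (at least 9.28-fold lower). All 6 supporting cell markers fell (camera adjusted p = 0.00149, adjusted p = 0.0411 with an estimated correlation), with Otog (at least 5.96-fold lower), Sox2 (at least 2.99-fold lower) and Slc1a3 (-1.05 ± 0.086) beside Gjb6. All 5 strial marginal cell markers fell (camera adjusted p = 0.00243, adjusted p = 0.0474 with an estimated correlation), with the endocytic receptor gene Lrp2 (-1.02 ± 0.045) and the potassium channel gene Kcnq1 (-1.33 ± 0.091) among them. The 3 hair cell markers, Otof (at least 3.20-fold lower), Myo7a (at least 1.11-fold lower) and Lhfpl5 (at least 1.37-fold lower), also fell (camera adjusted p = 0.0464, adjusted p = 0.112 with an estimated correlation). That call ended without fresh array C (adjusted p = 0.0517), without incubated array C (adjusted p = 0.0544) and with quantile normalization (adjusted p = 0.0564). Melanocyte markers gave 4 falls, led by Dct (at least 4.50-fold lower), Mitf (-1.34 ± 0.075) and Ednrb (at least 1.42-fold lower), and 1 rise, Gpnmb (at least 2.38-fold higher) (camera adjusted p = 0.128). Markers of Schwann and satellite glia gave 4 falls and 1 rise of 5 (camera adjusted p = 0.248), each under 2-fold, such as Sox10 (-0.54 ± 0.060), Mal (-0.31 ± 0.042), Cnp (-0.72 ± 0.17) and Pmp22 (-0.23 ± 0.057), while another probe set of Mal rose. With hybridization-control scaling the list's median, Mal and Pmp22 turned positive and Cnp no longer passed. Without incubated array A the Cnp change was -0.44. The ratio of 3' to 5' signal of the beta-actin control was 4.12 ± 0.145 in fresh arrays, 1.91 ± 0.0492 in incubated arrays and 1.84 ± 0.0993 in dexamethasone arrays (SD, n = 3). For the Gapdh control it was 7.11 ± 0.356, 3.74 ± 0.237 and 5.26 ± 0.224, and exact permutation tests of 3 against 3 arrays cannot go below p = 0.1.

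Blood, immune, muscle, vessel and bone markers were counted in the same way. All 9 neutrophil markers fell (camera adjusted p = 8.71e-04, adjusted p = 0.0770 with an estimated correlation), among them Camp (-3.11 ± 0.12), S100a9 (-2.76 ± 0.14), S100a8 (-2.02 ± 0.13) and Mpo (at least 3.68-fold lower). Of 10 macrophage markers, 7 rose and 1 fell (camera adjusted p = 0.0257, adjusted p = 0.0838 with an estimated correlation): Cd68 (at least 8.23-fold higher), Adgre1 (1.37 ± 0.10) and Cd14 (0.92 ± 0.087) rose and Csf1r (-1.11 ± 0.064) fell. With hybridization-control scaling the macrophage list missed the threshold (adjusted p = 0.0663). All 6 striated muscle markers fell (camera adjusted p = 0.00420, adjusted p = 0.0804 with an estimated correlation), such as Myh1 (at least 3.68-fold lower) and Tnnc2 (at least 2.04-fold lower). The muscle, erythroid, bone and lymphocyte markers had means under 200 in both cultured groups. They were tested through fresh arrays and could hardly rise, so their falls were favoured by the filter. Lists with fewer than 3 measured members had no list test. In these, the erythroid genes Slc4a1 (at least 9.04-fold lower) and Alas2 (at least 5.77-fold lower), the endothelial genes Kdr (-2.30 ± 0.085) and Emcn (-0.17 ± 0.068), the bone genes Dmp1 (at least 2.08-fold lower) and Ctsk (-0.35 ± 0.13) and the lymphocyte gene Ighm (at least 2.45-fold lower) fell. Emcn passed in none of the fits that left out 1 array (-0.18 to -0.14), and turned positive with hybridization-control scaling. Ctsk did not pass without fresh array A (-0.30), fresh array C (-0.31) or incubated array B (-0.30), or with quantile normalization (-0.11) or hybridization-control scaling (-0.040). Among the genes given here the adjusted p was at most 0.0420. All counts in this and the preceding list of cell types were the same adjusted over the list alone.

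In total 6620 probe sets were higher and 7593 lower in incubated than in fresh arrays, of which 1435 and 2197 changed at least 2-fold. By gene, 3691 were higher and 4171 lower, 743 and 1308 of them at least 2-fold. The 3 arrays of each group did not overlap for 8011 genes (78.2%), where chance gives 10%. With hybridization-control scaling, which raised the median change of all genes by 0.342, the split became 10166 higher and 4372 lower (69.9% higher, against 46.6%), and 2952 and 1388 at least 2-fold. Changes smaller than that shift therefore have no settled direction.

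**Figure D1:**
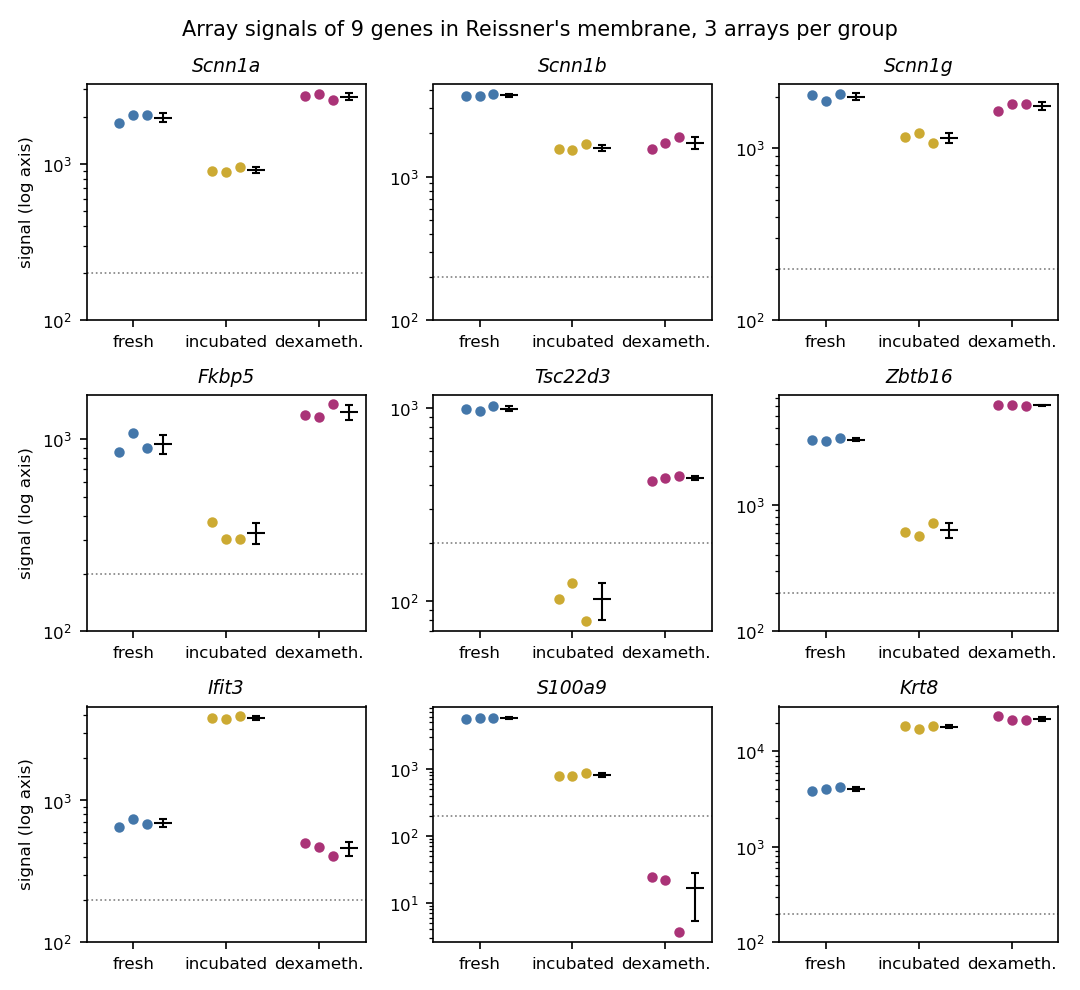
Array signals on a log axis (arbitrary units) of 9 genes in fresh, incubated and dexamethasone arrays, 3 per group, with each point 1 array, black bars the mean ± SD and the dotted line a signal of 200. Scnn1a lay near 1982, 918 and 2692 in the 3 groups, and S100a9 fell below the line in all dexamethasone arrays.

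The second comparison set explants with dexamethasone against explants without it, and asked which transcripts the steroid changed. Zbtb16, a transcription factor gene, rose the most, from 629.6 ± 82.2 to 6088 ± 32.9 (SD, n = 3): Zbtb16 rose by 3.22 ± 0.073 (adjusted p = 2.93e-11). Dpep1 rose by 2.75 ± 0.12 (adjusted p = 4.69e-09), a membrane dipeptidase, and Saa3 rose by 2.69 ± 0.13 (adjusted p = 1.52e-08), an acute-phase protein gene. Genes raised from under the signal of 200 were Galnt15 (at least 6.63-fold higher), a glycosyltransferase, Sult1a1 (at least 2.56-fold higher), a sulfotransferase, Trim63 (at least 3.23-fold higher), a ubiquitin ligase, F13a1 (at least 3.05-fold higher), a coagulation factor subunit, and Vegfd (at least 1.44-fold higher), a vascular growth factor (adjusted p at most 5.62e-07).

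Most of the 8 largest falls with the steroid were in neutrophil and interferon-induced transcripts. The calgranulin genes S100a8 fell at least 7.96-fold (adjusted p = 3.78e-10) and S100a9 fell at least 4.09-fold (adjusted p = 7.57e-10), and the granule protein genes Ngp fell at least 3.60-fold (adjusted p = 7.93e-09) and Camp fell at least 1.50-fold (adjusted p = 1.70e-09). The S100a8 probe set may hybridize to more than one transcript. Of the interferon-induced genes, Rsad2 fell at least 8.25-fold (adjusted p = 8.47e-10), Usp18 fell at least 2.47-fold (adjusted p = 2.66e-07) and Ifit3 fell by 2.97 ± 0.080 (adjusted p = 1.25e-10), from 3824 ± 119 to 461 ± 52.0. Cndp1 fell by 3.01 ± 0.10 (adjusted p = 4.43e-10), a dipeptidase that cleaves carnosine.

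The fixed list of glucocorticoid receptor targets rose as a group, 25 of 27 genes, with 1 fall and 1 gene not past the test (camera adjusted p = 1.11e-12, adjusted p = 0.0333 with an estimated correlation). The same counts held adjusted over the list alone. With hybridization-control scaling 18 rose and 3 fell, and the median went from 0.93 to 0.58. Fkbp5, a chaperone that restrains the receptor, went from 325 ± 41.1 to 1389 ± 122, and Fkbp5 rose by 1.99 ± 0.10 (adjusted p = 2.30e-08). Tsc22d3 rose at least 2.17-fold (adjusted p = 1.16e-07), the glucocorticoid-induced leucine zipper, and Per1 rose by 1.05 ± 0.10 (adjusted p = 2.55e-06), a clock gene. Rises of at least 2-fold were also seen for Ampd3 (1.57 ± 0.077), Map3k6 (1.27 ± 0.15), Pdk4 (1.19 ± 0.078), Klf15 (1.17 ± 0.070), Cebpd (1.17 ± 0.049) and Lcn2 (1.16 ± 0.053) (adjusted p at most 1.80e-05). Smaller rises were those of Rgs2 (0.93 ± 0.10), Cebpb (0.85 ± 0.057), Glul (0.82 ± 0.048), Dusp1 (0.66 ± 0.062), Klf9 (0.60 ± 0.060) and Gadd45g (0.51 ± 0.10) (adjusted p at most 0.00114). Errfi1 (0.35 ± 0.043), Cdkn1c (0.35 ± 0.084), Anxa1 (0.32 ± 0.052), Nfkbia (0.32 ± 0.049), Mt2 (0.21 ± 0.081) and Mt1 (0.20 ± 0.053) also rose (adjusted p at most 0.0489). With hybridization-control scaling Anxa1, Nfkbia, Mt1 and Mt2 turned negative and Errfi1, Cdkn1c and Gadd45g no longer passed. Quantile normalization ended the calls of Mt1 (0.080) and Mt2 (0.083). The Mt2 call also ended without incubated array B (0.15), incubated array C (0.22), dexamethasone array A (0.18) or dexamethasone array C (0.18). Ddit4 fell by 1.23 ± 0.082 (adjusted p = 2.04e-07), which encodes an inhibitor of mTOR signalling. The cochaperone gene Fkbp4 (-0.16 ± 0.075, adjusted p = 0.0897) passed as a fall only without dexamethasone array C (-0.25), with hybridization-control scaling (-0.51) and with the array letter as a block. Angptl4 rose at least 1.02-fold (adjusted p = 8.12e-05), a lipoprotein lipase inhibitor, and Hif3a stayed under a signal of 200 on average in both groups, so no change is given for it.

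Sodium transport genes did not move in one direction with dexamethasone. Of 21 genes, 9 rose, 7 fell and 5 did not pass the test, the same as adjusted over the list alone (camera adjusted p = 0.445). With hybridization-control scaling 5 rose and 13 fell, and the median was -0.42. Their median was -0.084 and their mean 0.16, of opposite sign, and the camera direction was up. The alpha subunit gene of the epithelial sodium channel, Scnn1a, went from 918 ± 36.3 to 2692 ± 132, and Scnn1a rose by 1.52 ± 0.063 (adjusted p = 4.29e-09). The gamma subunit gene Scnn1g rose by 0.60 ± 0.065 (adjusted p = 1.07e-05), while the beta subunit gene Scnn1b (0.11 ± 0.066, adjusted p = 0.180) did not pass the test, except without dexamethasone array A (0.17). Wnk4 rose by 1.88 ± 0.10 (adjusted p = 2.17e-08), Kcnk1 rose by 1.10 ± 0.062 (adjusted p = 4.74e-08) and Usp2 rose by 0.87 ± 0.060 (adjusted p = 2.66e-07). The sodium pump beta subunit genes Atp1b1 (-0.33 ± 0.045), Atp1b2 (-0.53 ± 0.068) and Atp1b3 (-0.59 ± 0.088) and the pump modulator Fxyd5 (-0.61 ± 0.095) fell (adjusted p at most 1.84e-04). The receptor genes Nr3c2 (-0.53 ± 0.062) and Nr3c1 (-0.20 ± 0.072) and the kinase gene Sgk1 (-0.15 ± 0.052) fell (adjusted p at most 0.0351). The Nr3c1 call ended without incubated array B (-0.17), incubated array C (-0.17) or dexamethasone array A (-0.15), and the Sgk1 call without incubated array A (-0.12), dexamethasone array A (-0.15) or dexamethasone array B (-0.13). Wnk1 (0.26 ± 0.050), Pik3r1 (0.22 ± 0.071), Nedd4l (0.18 ± 0.047) and the channel-activating protease gene Prss8 (0.13 ± 0.050) rose (adjusted p at most 0.0487), and all 4 turned negative with hybridization-control scaling. The Pik3r1 call ended without incubated array C (0.19), dexamethasone array B (0.20) or dexamethasone array C (0.21), and the Prss8 call without any 1 of incubated arrays B and C and dexamethasone arrays A to C (0.11 to 0.15). The log2 changes of Stk39 (-0.17 ± 0.078, adjusted p = 0.0831), Fxyd1 (-0.11 ± 0.076, adjusted p = 0.230) and Fxyd6 (-0.084 ± 0.10, adjusted p = 0.524) did not pass, except as falls without dexamethasone array C for Stk39 (-0.23), incubated array B for Fxyd1 (-0.21) and incubated array A for Fxyd6 (-0.22), and for all 3 with hybridization-control scaling. Testing probe sets of every signal ended the Nr3c1, Sgk1 and Prss8 calls, and quantile normalization that of Pik3r1 (0.18). Hsd11b1 lay under a signal of 200 in both groups.

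Complement, MHC and interferon genes and neutrophil markers were lower with the steroid, and inflammatory genes moved both ways. Of 19 complement, MHC and interferon genes, 15 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 2.46e-05, adjusted p = 0.0333 with an estimated correlation). Ifit1 (-2.78 ± 0.066), Oas1a (-0.95 ± 0.061) and the complement protease gene C1s1 (-1.27 ± 0.068) fell beside Ifit3, and Serping1 (0.34 ± 0.057), the C1 inhibitor, rose but turned negative with hybridization-control scaling. Of 17 inflammatory genes, 8 fell, 5 rose and 4 did not pass the test, also the same adjusted over the list alone (camera adjusted p = 0.445). The adhesion gene Vcam1 (-1.21 ± 0.075) and the chemokine genes Ccl5 (-2.07 ± 0.14), Cxcl2 (at least 2.80-fold lower) and Ccl2 (-1.27 ± 0.12) fell, and the chemokine Cxcl1 (1.81 ± 0.29) rose with Saa3. Of 9 neutrophil markers, 7 fell and none rose, likewise adjusted over the list alone (camera adjusted p = 0.00143, adjusted p = 0.123 with an estimated correlation), and none of the list reached a mean signal of 200 in dexamethasone arrays. With hybridization-control scaling the neutrophil list missed the threshold (adjusted p = 0.0706). Macrophage markers moved both ways, 4 up and 2 down of 10 (4 and 3 adjusted over the list alone; camera adjusted p = 0.634): C1qb (0.93 ± 0.076) and Csf1r (0.44 ± 0.064) rose and Adgre1 (-0.88 ± 0.10) and Lyz2 (-0.44 ± 0.055) fell. With hybridization-control scaling the macrophage median of 0.083 turned negative, with 2 rises and 5 falls, Csf1r no longer passed, and inflammatory genes gave 3 rises and 10 falls. The genes named here had adjusted p of at most 3.19e-04.

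Cell cycle and cholesterol synthesis genes were lower with dexamethasone. Of 15 cell cycle genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone; camera adjusted p = 5.94e-04, adjusted p = 0.0540 with an estimated correlation), with the replication genes Mcm3 (-0.92 ± 0.072), Mcm5 (-0.88 ± 0.077), Mcm7 (-0.61 ± 0.046) and Pcna (-0.53 ± 0.056). Of 16 cholesterol synthesis genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.0162, adjusted p = 0.120 with an estimated correlation), including Idi1 (-0.88 ± 0.065), Nsdhl (-0.63 ± 0.080), Fdft1 (-0.49 ± 0.049) and Msmo1 (-0.44 ± 0.053). That list missed the threshold with hybridization-control scaling (adjusted p = 0.0615). 14 of 21 immediate early genes rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.0637 with an estimated correlation), with Srf (0.87 ± 0.065), Klf6 (0.74 ± 0.067) and Jun (0.72 ± 0.060). With hybridization-control scaling 6 of them rose and 6 fell, and the median went from 0.40 to 0.073. Heat shock genes gave 10 rises and 1 fall of 18, the same adjusted over the list alone (camera adjusted p = 0.00732, adjusted p = 0.120 with an estimated correlation), led by Hspa1a (1.08 ± 0.062) and Hspb8 (0.52 ± 0.052). Oxidative stress genes gave 10 rises and no fall of 18, unchanged when adjusted over the list alone (camera adjusted p = 0.00963, adjusted p = 0.155 with an estimated correlation), with the catalase gene Cat (1.00 ± 0.054) and the glutathione genes Gstm1 (1.15 ± 0.066) and Gclc (0.92 ± 0.053). The medians of the heat shock list (0.25) and the oxidative stress list (0.18) turned negative with hybridization-control scaling, with 4 rises and 7 falls, and 4 rises and 8 falls. For the genes in this paragraph the adjusted p was at most 3.79e-05.

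Other pathway lists did not pass the list test with the steroid, although single members did. Of 25 oxidative phosphorylation genes, 11 fell and 3 rose (12 and 3 adjusted over the list alone; camera adjusted p = 0.141), such as Ndufs3 (-0.39 ± 0.049) and Uqcrfs1 (-0.40 ± 0.056), and the list passed with quantile normalization (adjusted p = 0.0289). Of 18 glycolysis and hypoxia genes, 5 rose and 8 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.811), with a negative median (-0.023), a positive mean (0.0067) and an upward test, and Ndrg1 (1.06 ± 0.051) as its largest rise. Of 25 unfolded protein and amino acid stress genes, 12 rose and 6 fell (camera adjusted p = 0.141), among them Mthfd2 (0.81 ± 0.058), Ddit3 (0.81 ± 0.058) and the disulfide isomerase gene Pdia6 (-0.59 ± 0.047). Of 15 clock genes, 7 rose, including Nfil3 (0.64 ± 0.11) and Nr1d1 (at least 1.15-fold higher), and 5 fell (camera adjusted p = 0.466). Potassium and chloride genes gave 3 rises and 6 falls of 12 (5 and 6 adjusted over the list alone; camera adjusted p = 0.651), with falls of Slc26a4 (-0.98 ± 0.066), Kcnk2 (-1.26 ± 0.093) and Kcnj13 (at least 1.39-fold lower). Calcium genes gave 3 rises, with Trpv4 (0.60 ± 0.064) and Atp2b1 (0.32 ± 0.045), and no fall of 12 (camera adjusted p = 0.204). Hybridization-control scaling turned Atp2b1 negative. Of 7 purinergic and other receptor genes, 2 rose, Piezo1 (0.66 ± 0.063) and P2rx2 (0.50 ± 0.050), and Panx1 (at least 1.69-fold lower) fell (camera adjusted p = 0.445). Where no such count is given, counts adjusted over the list alone were the same, and the medians of the unfolded protein, clock, calcium and receptor lists turned negative with hybridization-control scaling. With that scaling the rises and falls were 0 and 25 for oxidative phosphorylation (0 and 15 with quantile normalization), 1 and 13 for glycolysis, 4 and 13 for unfolded protein, 3 and 8 for clock, 1 and 7 for potassium and chloride, 1 and 6 for calcium and 2 and 4 for receptor genes. The genes named here had adjusted p of at most 6.21e-04.

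Matrix, junction and cell type lists made up the rest. Of 23 collagen and matrix genes, 10 rose and 7 fell (10 and 8 adjusted over the list alone; camera adjusted p = 0.405): the basement membrane collagens Col4a1 (1.41 ± 0.056) and Col4a2 (1.16 ± 0.11) rose and the fibrillar collagens Col3a1 (-2.24 ± 0.092) and Col1a2 (-0.78 ± 0.059) fell. Of 17 matrix protease and wound genes, 6 rose and 6 fell (camera adjusted p = 0.811), among them Lox (0.67 ± 0.052), Ccn2 (0.62 ± 0.049) and Tnc (at least 1.36-fold lower), with a positive median, an upward test and a negative mean (-0.16). Water channel and gap junction genes gave 4 rises and 3 falls of 8 (camera adjusted p = 0.711), with a positive median, an upward test and a negative mean (-0.13): Aqp1 (at least 2.25-fold lower) and Aqp5 (-1.68 ± 0.11) fell and Gjb6 (at least 1.27-fold higher) and Gjb2 (0.41 ± 0.056) rose. Of 20 junction genes, 11 rose, such as Tjp1 (0.40 ± 0.044) and Cldn9 (0.40 ± 0.047), and 3 fell, led by Cldn8 (-1.01 ± 0.068) (camera adjusted p = 0.0914). Of 11 epithelial markers, 7 rose, including Krt7 (0.65 ± 0.089) and Krt19 (0.35 ± 0.051), and Epcam (-0.31 ± 0.042) fell (camera adjusted p = 0.0695), and mesothelial and fibroblast markers gave 3 rises, with Gsn (0.39 ± 0.039), and 5 falls of 12 (camera adjusted p = 0.634). The medians of these lists other than the mesothelial one turned negative with hybridization-control scaling, and Gjb2, Tjp1, Cldn9, Krt19 and Gsn no longer passed. The rises and falls were then 6 and 11 for collagen and matrix, 3 and 11 for protease, 2 and 4 for water channel, 1 and 10 for junction, 1 and 5 for epithelial and 1 and 7 for mesothelial genes. Before that scaling the adjusted p of the genes in this paragraph was at most 9.87e-05.

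Supporting cell markers gave 5 rises of 6 (camera adjusted p = 0.0217, adjusted p = 0.123 with an estimated correlation), with Otog (at least 1.19-fold higher) beside Gjb6. With hybridization-control scaling 3 of them rose, and the median went from 0.55 to 0.26. Schwann and satellite glia markers gave 3 rises of 5 (4 adjusted over the list alone; camera adjusted p = 0.0296, adjusted p = 0.155 with an estimated correlation), among them Pmp22 (0.62 ± 0.057), Mal (0.28 ± 0.042) and Mbp (0.28 ± 0.046), genes of myelin. The glial call ended without incubated array A (adjusted p = 0.0588) and with hybridization-control scaling (adjusted p = 0.135), which also turned the median, Mal and Mbp negative. Of 8 fibrocyte markers, 4 rose and 2 fell (camera adjusted p = 0.216), with rises of Pou3f4 (1.41 ± 0.056), Coch (at least 2.02-fold higher) and Otos (at least 1.62-fold higher). Strial marginal markers gave 2 falls of 5, Kcnq1 (-0.39 ± 0.091) and Atp1b2 (camera adjusted p = 0.657), and melanocyte markers 1 rise of 5 (camera adjusted p = 0.634). Of 10 neuron markers, 1 rose and 2 fell (camera adjusted p = 0.811), and only Gap43 (at least 1.52-fold lower) had a mean of 200 in either group among those past the test. With hybridization-control scaling the rises and falls were 4 and 4 for fibrocyte, 0 and 4 for strial, 1 and 4 for melanocyte and 1 and 6 for neuron markers, and with quantile normalization 1 and 3 for melanocyte markers. The endothelial receptor gene Kdr (0.63 ± 0.085) rose. Every measured hair cell, muscle, erythroid, bone and lymphocyte marker had a mean under 200 in incubated and in dexamethasone arrays, so no change is given for them (camera adjusted p = 0.587 for hair cells and adjusted p = 0.967 for muscle). The muscle list had a negative median, a positive mean and an upward test, and quantile normalization turned the hair cell and receptor medians. Adjusted over the list alone, counts in this and the preceding paragraph were otherwise the same. For the genes named in it the adjusted p was at most 0.00313.

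With dexamethasone 5116 probe sets were higher and 4820 lower than without it, of which 614 and 254 changed at least 2-fold. By gene, 2280 were higher and 2937 lower, 181 and 154 of them at least 2-fold. Of 1849 probe sets with no gene symbol here, 237 (12.8%) were at least 2-fold higher and 17 (0.919%) at least 2-fold lower, against 1.77% and 1.50% of the probe sets that stood for genes. Those were chosen for the highest signal of each gene. For the other probe sets of genes the shares were 3.03% and 1.12%. The 3 arrays of each group did not overlap for 5931 genes (57.9%), where chance gives 10% only if all arrays are independent. Hybridization-control scaling lowered the median change of all genes, whose shift was -0.334, and gave 1896 higher and 11460 lower (14.2% higher, against 51.5%), and 211 and 772 at least 2-fold. With quantile normalization the counts of at least 2-fold were 452 higher and 293 lower (60.7% higher, against 70.7%).

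**Figure D2:**
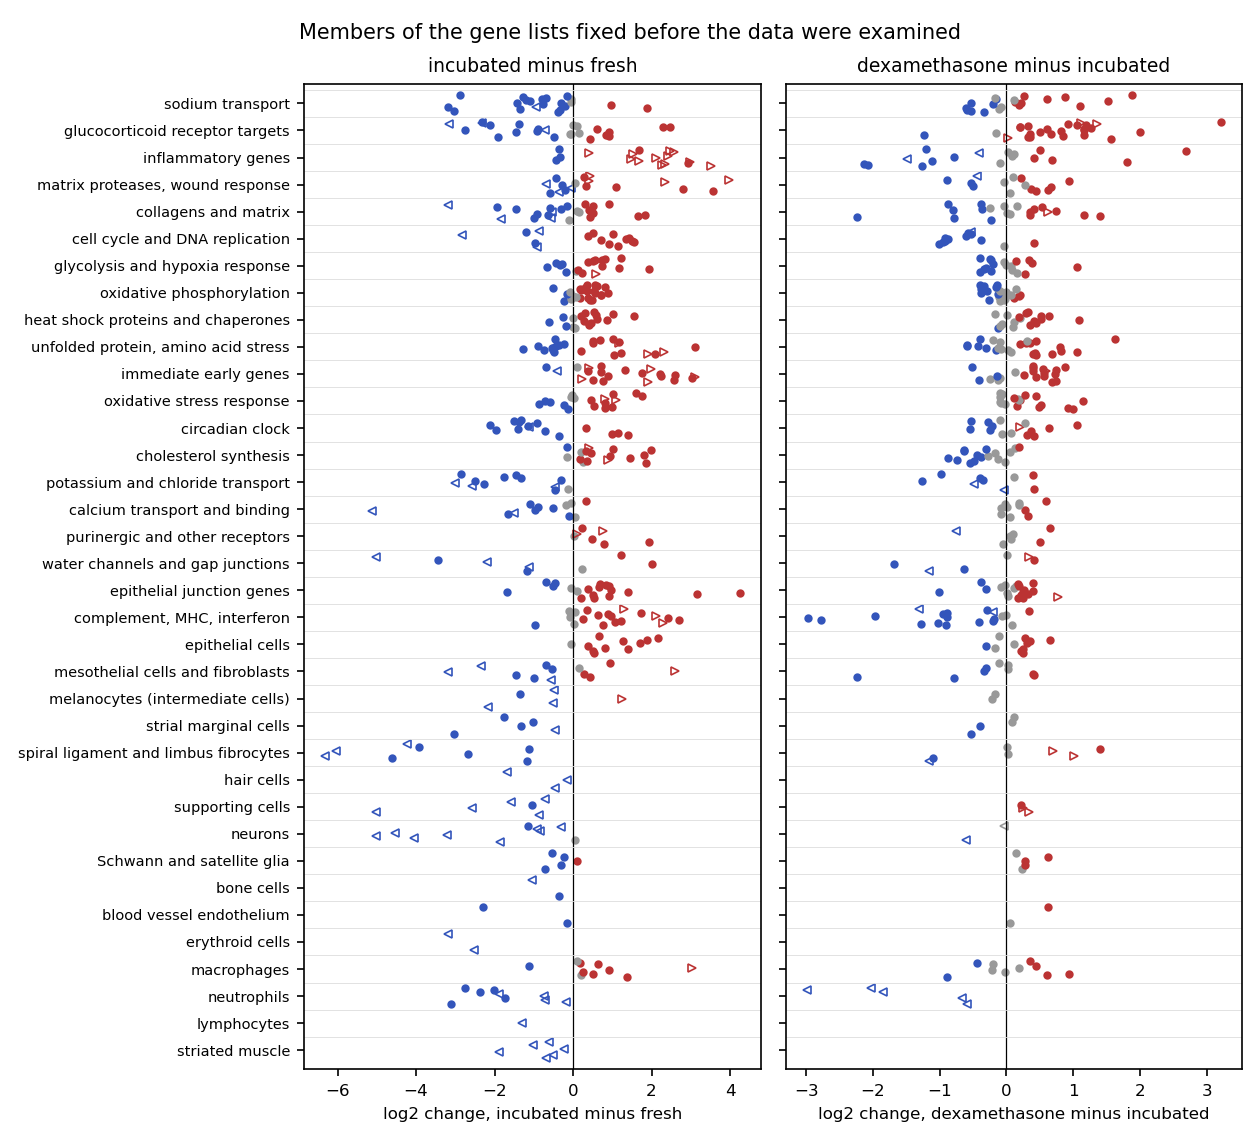
Log2 change of each list member, incubated minus fresh in one panel and dexamethasone minus incubated in the other, with one line of points per gene list. Red points were called higher, blue points lower and grey points did not pass the test; open triangles are drawn at their lower bound, and genes with both group means under a signal of 200 are left out.

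Dexamethasone arrays were also set against fresh arrays, a secondary comparison that joins culture and steroid. The subunit gene Scnn1a (0.44 ± 0.063, adjusted p = 3.50e-05) was above its fresh level, while Scnn1b (-1.09 ± 0.066, adjusted p = 8.33e-09) and Scnn1g (-0.18 ± 0.065, adjusted p = 0.0256) were below theirs. The Scnn1g call ended without fresh array A (-0.17), fresh array C (-0.15) or dexamethasone array A (-0.13). The receptor target Fkbp5 (0.54 ± 0.10, adjusted p = 3.52e-04) lay above its fresh level, and Tsc22d3 (-1.14 ± 0.11, adjusted p = 9.88e-07) and Per1 (-1.08 ± 0.10, adjusted p = 3.37e-07) lay below theirs. The receptor genes Nr3c1 (-0.97 ± 0.072, adjusted p = 6.27e-08) and Nr3c2 (-0.83 ± 0.062, adjusted p = 6.17e-08) were lower than in fresh tissue. In all, 7156 probe sets were higher and 7263 lower, 1721 and 2365 of them at least 2-fold, and by gene 3625 were higher and 4375 lower, 823 and 1498 at least 2-fold.

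The changes in culture and with the steroid were then compared across genes. Of the receptor targets, 13 had fallen on incubation and all 13 of them rose with dexamethasone, as did 7 of the 8 that had risen on incubation. With 25 of 27 targets higher with dexamethasone, the rise was not particular to those that fell in culture. Zbtb16 went from 3261 to 629.6 to 6088 over the fresh, incubated and dexamethasone groups, and the interferon gene Ifit1 from 479 to 3301 to 452. Of genes changed at least 2-fold in both comparisons, 88 fell in culture and rose with the steroid, where independent lists would share 23.1. Another 39 rose and then fell (11.2 for independent lists), 17 rose in both (13.1) and 40 fell in both (19.7). By call alone the counts were 1106 (929), 1234 (1058), 729 (822) and 1095 (1196). The incubated arrays enter both comparisons. Across genes, which are not independent replicates, Pearson's r between the changes was -0.133 and Spearman's rho -0.096, where simulated unchanged groups gave a mean r of -0.5. The covariance was -0.057, against a mean of -0.00512 in the simulated groups (-0.00581 to -0.00464), a difference of -0.052. With the incubated arrays divided so that none entered both comparisons, a check chosen after the results were seen, the covariance over the 6 divisions was -0.057 to -0.046. Such a division does not part what arrays of the same pool share.

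**Figure D3:**
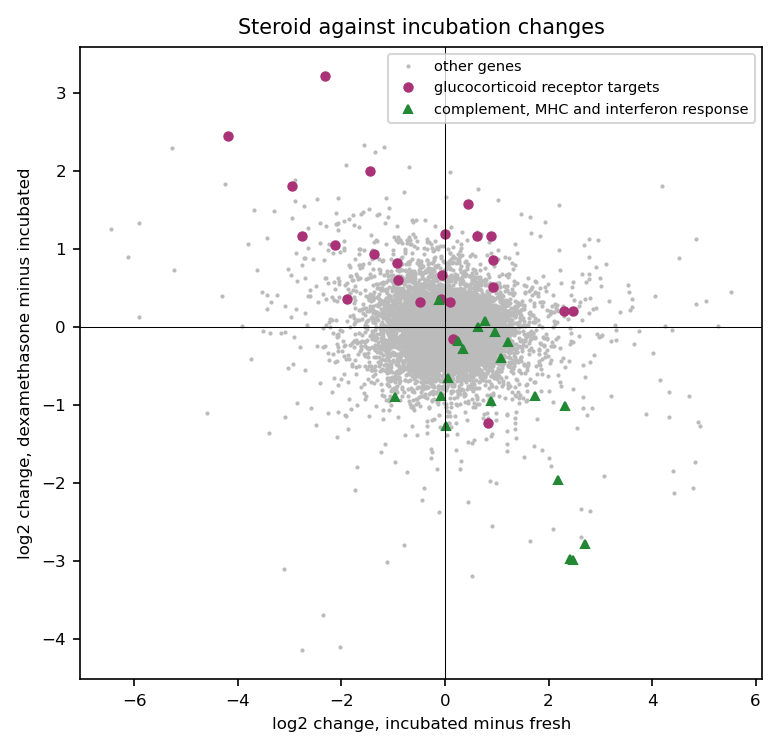
Log2 change on incubation (incubated minus fresh, x axis) against log2 change with the steroid (dexamethasone minus incubated, y axis) for 9321 genes, each point a gene, with 24 glucocorticoid receptor targets as circles and 19 complement, MHC and interferon genes as triangles. Genes under a signal of 200 in both groups of either comparison are left out.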

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

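The test of RNA quality in fresh arrays was chosen after its result was seen, as were the comparison of abundant with other glial genes, the look at macrophage markers and the medians with bounds, in which changes against a group under 200 are held to that level. Control probe sets were outside the comparisons and were looked at for a signal at least 1.5 times higher in one group, with no overlap of arrays and a mean of 200 or more in the higher group. The transferrin receptor controls lay under that mean and were left out. The 5' beta-actin control was 1.77 times higher in incubated than in fresh arrays. The 5' Gapdh control was 2.16 times higher and the middle Gapdh control 1.74 times higher in the same comparison. The MUR_b2 control was 1.83 times higher in dexamethasone than in incubated arrays. In the other direction, the 3' pyruvate carboxylase control was 2.47 times higher in fresh than in incubated arrays.

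Neutrophil marker transcripts were lower with dexamethasone, with a list median of -0.851 with bounds (95% bootstrap interval -2.03 to 0.185). Intervals here and below resampled the genes of a set (2000 draws), not arrays or pools. They describe the spread among genes, which are not independent replicates, and not the precision of an effect across animals. 5 further neutrophil genes outside the list had 3 falls and a median of -0.564 (-1.43 to 0.197). Of these, Prtn3, Pglyrp1 and Cd177 had means under the floor in both groups, and the median was that of Pglyrp1. Chil3 went from 298 to 97.2, and Chil1 (568 to 560) was not called. Less marrow or blood in the treated pool could account for this, and stayed open: 9 further erythroid genes had a median of -0.224 (-0.457 to -0.064), and 7 of them lay under the floor in both groups. A general leukocyte loss also stayed open, since the interval of 12 leukocyte-wide genes (median -0.481, -0.769 to 0.227, 6 lower and 2 higher) overlapped that of the neutrophil list. The 10 macrophage markers had 4 rises, 2 falls and a median of 0.083 (-0.32 to 0.476), which went to -0.256 with hybridization-control scaling. Their interval overlapped both others, so they do not decide it. An effect of the steroid on neutrophils cannot be told apart from these 2 with genes so near the floor.

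Interferon response genes were lower with dexamethasone. Of 21 further interferon-induced genes listed, 10 were tested. Of these 9 fell, with a median of -0.803 (-1.28 to -0.56), which is what a response shared by interferon-induced genes would give. Oasl2 had a mean above the floor in incubated arrays alone (338.9, against 131.8 in fresh and 98.1 in dexamethasone arrays). Testing it through incubated arrays favours its rise on incubation and its fall with dexamethasone. Each of the others also had a mean above the floor in fresh or dexamethasone arrays. The same 10 had all risen on incubation (0.988), but the incubated arrays enter both comparisons, so that rise is no independent support. A deviation of the incubated pool itself cannot be told apart from an effect of the steroid here. Fewer leukocytes in the treated pool could give falls too, and the leukocyte-wide median of -0.481 had an interval that overlapped theirs, so this stayed open. The macrophage markers, as above, had a median of 0.083 (-0.32 to 0.476), or -0.256 with hybridization-control scaling. Their interval lay above that of the interferon genes but overlapped that of the leukocyte-wide genes, so they do not decide it. The leukocyte-wide genes had 9 falls and 1 rise on incubation (median -0.672), when the interferon genes rose.

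Neuronal and fibrocyte transcripts were lower in incubated than in fresh arrays, with list medians with bounds of -1.51 and -4.08. Over both lists the median with bounds was -2.943 (-4.30 to -1.16), opposite to the 5' Gapdh control, which rose by 1.11. Poorer RNA in the fresh arrays would lower fresh signals far from the 3' end. Each array was scaled to the same mean, so other fresh signals could be raised and then appear to fall on incubation. From fresh to incubated arrays, the 3' pyruvate carboxylase control went from 754 to 305 and 3' beta-actin from 29415 to 24196. The 3' Gapdh control went from 15637 to 17767. The opposite sign therefore decides nothing about RNA quality. Whether RNA quality had a part in the falls or rises on incubation was not tested. Less adjoining nerve in the incubated pool stayed open, since 8 further glial genes all fell, with a median of -1.825 (-2.75 to -0.296; -0.675 with bounds), and 14 further neuronal genes had 13 falls and 1 rise (-2.70, -3.38 to -2.00; -1.01 with bounds). Several genes of both sets, such as Fa2h and Scn8a, lay under 200 in both cultured groups and were tested through fresh arrays. This favours falls. When glial genes were parted by signal, 0 of 7 abundant ones (fresh signal of 1000 or more) fell 2-fold, while 5 of 6 others did. Among those others, Art3 went from 231.6 to 35.4, so its fall reached 2-fold only below the floor. Whether the abundant genes come from glia alone was not tested, so this does not decide the question. Loss of neurons and fibrocytes in culture was not tested separately.

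Splits of the 6 arrays of each comparison into 3 and 3 number 10, too few for a share under 0.05. The real split alone, 1 of 10, gave as many probe sets in each comparison. The real counts were 14213 for incubated against fresh, 9936 for dexamethasone against incubated and 14419 for dexamethasone against fresh, and the highest of the other splits gave 0, 1 and 0. Each other split mixes arrays of both groups, which widens the spread on each side. Low counts there were thus largely fixed in advance, and they say nothing about differences between pools.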

How the results depend on the processing

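Hybridization-control scaling and the division of the incubated arrays were chosen after the data were seen, and the other alternatives were planned. The scaling rests on 9 control probe sets, and whether it or the whole-array target is nearer to the RNA amounts was not tested. With the scaling 5 called changes on incubation changed sign: Emcn (0.18), Mal (0.051), Nr3c2 (0.055), Pmp22 (0.12) and Vcam1 (0.00062). With dexamethasone 12 did: Anxa1 (-0.033), Atp2b1 (-0.036), Mal (-0.073), Mbp (-0.070), Mt1 (-0.15), Mt2 (-0.15), Nedd4l (-0.17), Nfkbia (-0.035), Pik3r1 (-0.11), Prss8 (-0.22), Serping1 (-0.0082) and Wnk1 (-0.092). The scaling itself moves all genes one way, by 0.342 and -0.334. No other alternative turned the sign of a named gene that was called, and no list that passed changed direction in the camera test. With the scaling the medians of the heat shock, oxidative stress and Schwann glia lists with dexamethasone turned negative.

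With 1 probe set per gene, where fewer probe sets are tested, the counts were 7895 (2051 at least 2-fold) on incubation, 5221 (335, of them 181 higher and 154 lower) with dexamethasone and 8023 (2321) for dexamethasone against fresh. A pseudocount of 100, which shrinks changes at low signal, gave 465 probe sets changed 2-fold with dexamethasone (312 higher, 153 lower) in place of 868. With camera's estimated correlation 11 lists in place of 22 passed on incubation, and 2 in place of 10 with dexamethasone, and fry, which tests members without a background, gave 26 there. Hybridization-control scaling brought past the threshold the water channel (0.0156) and melanocyte (0.0209) lists on incubation, and the collagen (0.0204), oxidative phosphorylation (0.0103) and fibrocyte (0.0169) lists with dexamethasone (adjusted p, camera in limma). Leaving out 1 array at a time gave 13556 to 13647, 8822 to 9184 and 13837 to 13930 probe sets in the 3 comparisons, and an opposition covariance of -0.064 to -0.054, and dividing the incubated arrays gave a mean of -0.051. Calls that ended in fits of all probe sets or under changes of centring, pseudocount, floor, variance prior or number of groups were those of Mt2, Prss8, Nr3c1 and Sgk1 with dexamethasone, of Emcn and Ctsk on incubation, and of Scnn1g for dexamethasone against fresh with median centring (-0.14); the cause was not tested. With a floor of 400 some named genes were no longer tested.

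With the array letter as a replicate block, 14130, 9811 and 14369 probe sets were called and 3632, 868 and 4086 changed 2-fold, and the lists that passed were the same. With the block Emcn on incubation and Mt2 and Prss8 with dexamethasone were past the threshold no longer, and Fkbp4 passed (-0.16). Arrays of the same letter had deviations that correlated at -0.062 to 0.164, with 1 of 9 pairs over 0.1, and 0 arrays correlated best with their own letter in both other groups. Low signal limits what can be seen, since probe sets that reached 200 on fewer than 3 arrays were not tested.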
